A study of Mus musculus with 2 samples.

How the data were processed

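H3K36me3 ChIP-seq was done on midbrain of B6NCrl mouse embryos at embryonic day 10.5, in 2 biological replicates that each pooled embryos of both sexes, 69 in replicate 1 and 51 in replicate 2, per the labels. The labels give a fragment size range of 300 to 500 without naming its unit. Per the file headers and the labels, peaks were called on the mm10 assembly. The authors deposited a peak list for each replicate, a list from both replicates pooled, and a replicated list, which is a subset of the pooled one. Per the file headers, the list of replicate 1 derives from its own alignment and further files that differ in number from those of replicate 2. The roles of these further files, the aligner, the peak caller and their versions are not given in the sources used here, and the labels name a possible control experiment that was not analysed here.

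Each deposited peak has a signal value, a −log10 p and a −log10 q from the authors' peak caller. No listed peak has a −log10 p under 2, so the deposited lists are permissive: 76.1% of replicate 1 peaks and 83.9% of replicate 2 peaks have a −log10 q of at least 2. The signal values were used within a list only, to describe, rank and filter peaks and genes, to match genes, and in the tests of X-linked and zinc finger genes. The lists hold no read counts, so the depth per sample is unknown and no counting interval was attached to covered lengths. A list with more reads behind it yields more and wider peaks, which is a limit on every comparison between both replicates. Replicates are described by both values or by mean ± SD with n = 2.

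Overlapping intervals were merged within a list, and covered bases were counted on the autosomes and X. Genes came from GENCODE M21, on the same assembly, and chromosome lengths from its RefSeq annotation. A gene body ran from the annotated gene start to its end, and the covered share is the percentage of its bases in peaks. A gene was called marked at 25% or more in both replicates. The signal value of a gene is the mean over its covered bases. Profiles used genes of at least 10 kb, divided into 10 equal parts in the direction of transcription, with 5 kb on either side. Covered bases were assigned to promoters (within 1 kb of a transcription start site), then exons, introns and intergenic sequence. Randomly placed peaks were made by 100 circular shifts of each chromosome's peaks, leaving out the first 3 Mb of unknown sequence. Domains were peaks of the replicated list joined at 3 kb or less, and those outside genes lay more than 5 kb from any annotated gene.

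The 32 gene lists were fixed before the data were examined: midbrain and isthmus patterning, neural progenitors, early, dopaminergic and mature neurons, glia, forebrain patterning, neural crest and mesenchyme, endothelium, blood and macrophages, liver, striated muscle, epidermis, pluripotency, Polycomb-regulated regulators, Hox, histone, protocadherin, zinc finger, imprinted, cell cycle, H3K36 machinery, reference, ribosomal, mitochondrial ribosomal, proteasome, initiation factor, spliceosome, olfactory and vomeronasal receptor, keratin and defensin genes. For each list the median covered share was placed among 10000 random lists of the same size, drawn from protein-coding genes in the same of 20 bins of gene length. Percentiles above 97.5 or below 2.5 are called high or low, and they describe these libraries and are no p-values. Named genes were set by a rule written in advance: all midbrain patterning genes, up to 4 members of every other list (the 2 highest and the 2 lowest in covered share), the 10 genes of at least 10 kb with the highest covered share times signal value (mean rank over both replicates), the genes in the 10 widest domains, and the 5 genes with the largest difference between replicates in each direction. The comparison of numbers of marked genes with random lists was added after seeing the data.

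Alternatives set in advance changed the peak threshold (−log10 q of at least 2, or signal value of at least 3), the number of peaks per replicate, the overlap that counts as shared, the promoter width, the marked threshold (10% or 50%), the genes used, the matching and summary of random lists, the joining distance, and the use of the pooled or replicated list, and left out each replicate in turn. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1, with a difference of 0 peaks. Coverage was tested on simulated data: over 2000 genes with known covered shares the largest error was 0 percentage points, 100% of 1206 genes simulated at 40% or more and 0% of 794 genes at 15% or less were called marked, and a simulated 3-fold rise along 394 genes came back as 2.95-fold. Only genes of at least 10 kb that overlap no other gene were simulated. None was simulated between 15% and 40%, so calls near the 25% threshold were not tested. Of 100 random lists of 25 genes, 3% lay above the 97.5th percentile and 0% below the 2.5th. Of 100 lists of 25 genes with 60% of members drawn from marked genes, 100% lay above the 97.5th percentile. Most members of these lists were covered over 25% or more by choice, so this outcome was fixed in advance. It says nothing of weaker differences. Peaks on the Y chromosome and unplaced sequence were left out of all comparisons.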

Results

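H3K36me3, the trimethylated form of lysine 36 on histone H3, is laid down along gene bodies during transcription. It was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in midbrain dissected from B6NCrl mouse embryos of mixed sex at embryonic day 10.5. The series holds 1 group with 2 biological replicates, a pool of 69 embryos (replicate 1) and a pool of 51 embryos (replicate 2). The deposited data were peak lists on mm10, and replicate 1 held 341396 peaks and replicate 2 held 285007. The lists give no read counts, so the sequencing depth behind them is unknown. The labels describe no second tissue, stage or condition, so values are set against the annotation, against randomly placed peaks and between both replicates. The question addressed was which genes and regions carried the mark in both embryo pools.

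Genes for proliferation and for the gene expression machinery had high covered shares, with list medians from 49.4% to 79.4% of the gene body, whereas 9238 of 21755 protein-coding genes on the autosomes and X (42.5%) held no base in a peak of either replicate. A gene was called marked where at least 25% of its body lay in peaks in both replicates, and 5973 genes (27.5%) met this. Of these, 3277 were covered over at least 50% in both replicates. Of the marked genes 2665 overlap no other annotated gene, and for the others, Top2a, Msi1, Rest, Crmp1, Tubb3, Otx2 and Cnp among them, peaks cannot be assigned to one gene alone. The marked share depended on gene length. It was 2.73% of genes shorter than 1 kb, 7.22% at 1 to 2 kb, 38.4% at 10 to 20 kb and 1.70% at 200 kb or longer. A share of 0 in a short gene, here and below, therefore does not show that the gene was silent. Olfactory receptor genes, which are silent outside the olfactory epithelium in most tissues, were taken as the background. None of 1135 was marked and 1134 held no base in a peak. The exception was Olfr543 (13.6% covered in replicate 1 and 0 in replicate 2). None of 327 vomeronasal receptor genes held any base in a peak. Reads shared between members of these families were not examined, so this background may not hold for other genes. The number of marked genes was 7222 in replicate 1 alone and 5991 in replicate 2 alone.

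Cell cycle and DNA replication genes were the most fully covered of the 32 gene lists. Of the 30 genes, 29 were marked, where length-matched random lists held 5 to 15 (central 95% of random lists), and their median covered share was 79.4%. Top2a, the DNA topoisomerase that untangles replicated chromosomes, was covered over 91.5 ± 1.2% of its body (mean ± SD, n = 2; chromosome 11, 98992943 to 99024189). Bub1b, a spindle checkpoint kinase, reached 91.1 ± 0.9% and Pcna, the sliding clamp of DNA polymerase, 47.8 ± 4.0%. Pola1, the catalytic subunit of DNA polymerase alpha and an X-linked gene of 327.4 kb, was the only member not marked, at 5.79 ± 2.27%.

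Genes for RNA splicing, translation and protein turnover followed. Of 67 spliceosome and SR protein genes, 62 were marked with a median covered share of 69.98%, led by Sf3b3 (94.6 ± 0.6%) and Sf3a1 (93.0 ± 0.9%), both components of the particle that recognises the branch point. Among translation initiation factors 46 of 54 were marked (median 67.6%), with Eif4g2 at 91.3 ± 0.1% and Eif3c at 89.2 ± 1.0%. Of 39 proteasome genes 30 were marked (63.2%), of 83 ribosomal protein genes 68 (59.1%), of 75 mitochondrial ribosomal protein genes 54 (49.4%) and of 20 common reference genes 15 (57.6%). Within these lists, paralogs known for restricted expression stood at 0 in both replicates: the immunoproteasome subunits Psmb8 and Psmb9, the muscle ribosomal protein gene Rpl3l, Rpl39l, and the oocyte factor gene Eif4e1b. So did Mrpl41 (0.982 kb), Mrpl53 (0.900 kb), the core splicing gene Sf3b5 (3.84 kb) and Eif3j2 (2.38 kb), so a share of 0 was not limited to restricted paralogs. All of these list medians exceeded every one of 10000 length-matched random lists. Genes that write, erase or read methylation at H3K36 were marked in 18 of 24 cases (60.4%), among them the demethylase gene Kdm4a (91.4 ± 1.0%) and Psip1 (87.0 ± 2.2%), whose product binds the mark. Setd2, which encodes the main H3K36 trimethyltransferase and was named after its value was seen, was covered over 64.2 ± 6.0%.

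Of 26 neural progenitor genes 13 were marked (random lists 2 to 11), against 2 of 24 early neuron genes and none of 20 mature neuron genes. The progenitor list median of 34.3% lay at the 99.97th percentile of random lists. Msi1, an RNA-binding protein of neural stem cells, was covered over 89.6 ± 1.3% (chromosome 5, 115429599 to 115455698) and Rest, the repressor of neuronal genes, over 77.6 ± 5.2%. Zic3 (0.197 ± 0.279%) and Id1, a gene of 1.16 kb (0 in both replicates), were the lowest. Among the 11 progenitor genes that overlap no other gene 3 were marked, Vim, Nes and Id3, named after their values were seen. This number was not set against random lists. The other marked progenitor genes overlap other genes, so their peaks cannot be assigned to one gene alone. Of the early neuron genes only Crmp1 (46.4 ± 12.5%) and Tubb3, the neuronal beta tubulin (36.5 ± 11.8%), were marked, at the 1.59th percentile of random lists (2 to 11) by the number of marked genes, whereas the list median (3.95%) lay at the 66.1st percentile of random lists. Phox2a and Phox2b, homeobox genes of cranial motor and autonomic neurons, held no base in a peak. In replicate 1 alone 4 early neuron genes passed 25%, the others being Elavl3 and Dpysl3, and in both replicates Crmp1 alone did with peaks of signal value 3 or more.

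No gene was marked in the lists for dopaminergic neurons (12 genes), mature neurons and synapses (20), forebrain patterning (17), neural crest and mesenchyme (20), endothelium (14), blood and macrophages (18), liver (16), striated muscle (17) and epidermis (14). Th and Slc6a3, the tyrosine hydroxylase and dopamine transporter genes of mature dopaminergic neurons, held no base in a peak, nor did Slc32a1 and Pvalb of inhibitory neurons, Tbr1 of the cortex, Twist1 of mesenchyme, Tek of endothelium, Spi1 of myeloid cells, Afp of liver or Tnnt2 of heart muscle. Among 16 glial genes Cnp alone was marked (77.3 ± 3.6%), while Olig2 and Sox10 stood at 0. Cnp overlaps 1 other annotated gene, as do Msi1, Rest, Crmp1 and Tubb3, and Cx3cr1 (17.0 ± 1.5%) overlaps 9. Each of the 9 lists without a marked gene fell below the 2.5th percentile of random lists in its number of marked genes, as did the glial list at 1.39, a measure added after seeing the data because list medians of 0 tie with those of random lists.

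Among the 26 genes that pattern the midbrain and isthmus, only Otx2 was marked, where random lists held 2 to 10. Otx2, the homeobox gene of forebrain and midbrain (chromosome 14, 48657677 to 48673819), was covered over 37.9 ± 8.2% and overlaps 2 other genes. En2, a homeobox gene of midbrain and anterior hindbrain (chromosome 5, 28165694 to 28172166), reached 62.5% in replicate 1 and 24.1% in replicate 2, the widest gap in the list. Tal2 (26.4 ± 10.8%), Pax3 (23.0 ± 10.7%) and Pax7 (19.1 ± 12.4%), which act in midbrain GABAergic neurons and the dorsal neural tube, were partly covered in both replicates. Lower values were found at Foxa2 (14.6 ± 8.0%), Pax5 (12.9 ± 3.5%), Meis2 (12.8 ± 8.5%), Ascl1 (8.92 ± 7.59%), En1 (13.7% and 0), Msx1 (4.64 ± 1.38%), Nkx6-1 (3.51 ± 3.52%), Shh (3.18 ± 3.56%), Fgf17 (0 and 4.80%), Pax8 (1.98 ± 0.41%) and Lmx1b (1.15 ± 0.64%). Lmx1a, Gata2, Nkx2-2 and Pax2 held under 1% in replicate 1 and no base in replicate 2. Wnt1 and Fgf8, the signals of the isthmic organiser, and Gbx2, Neurog2, Pou4f1 and Sox14 held no base in a peak of either replicate. The shortest of these genes are Sox14 (2.065 kb) and Neurog2 (2.497 kb). In replicate 1 alone 5 genes of the list passed 25%: En2, Otx2, Tal2, Pax3 and Pax7. The list median (2.79%) lay at the 75.4th percentile of random lists. It was 2.96% in replicate 1 and 0.858% in replicate 2, at the 70.9th and 72.35th percentiles. The median and the number of marked genes thus pointed to different sides of the random lists. Among genes that overlap no other gene the median lay at the 97.55th percentile with none of 17 marked.

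**Figure D1:**
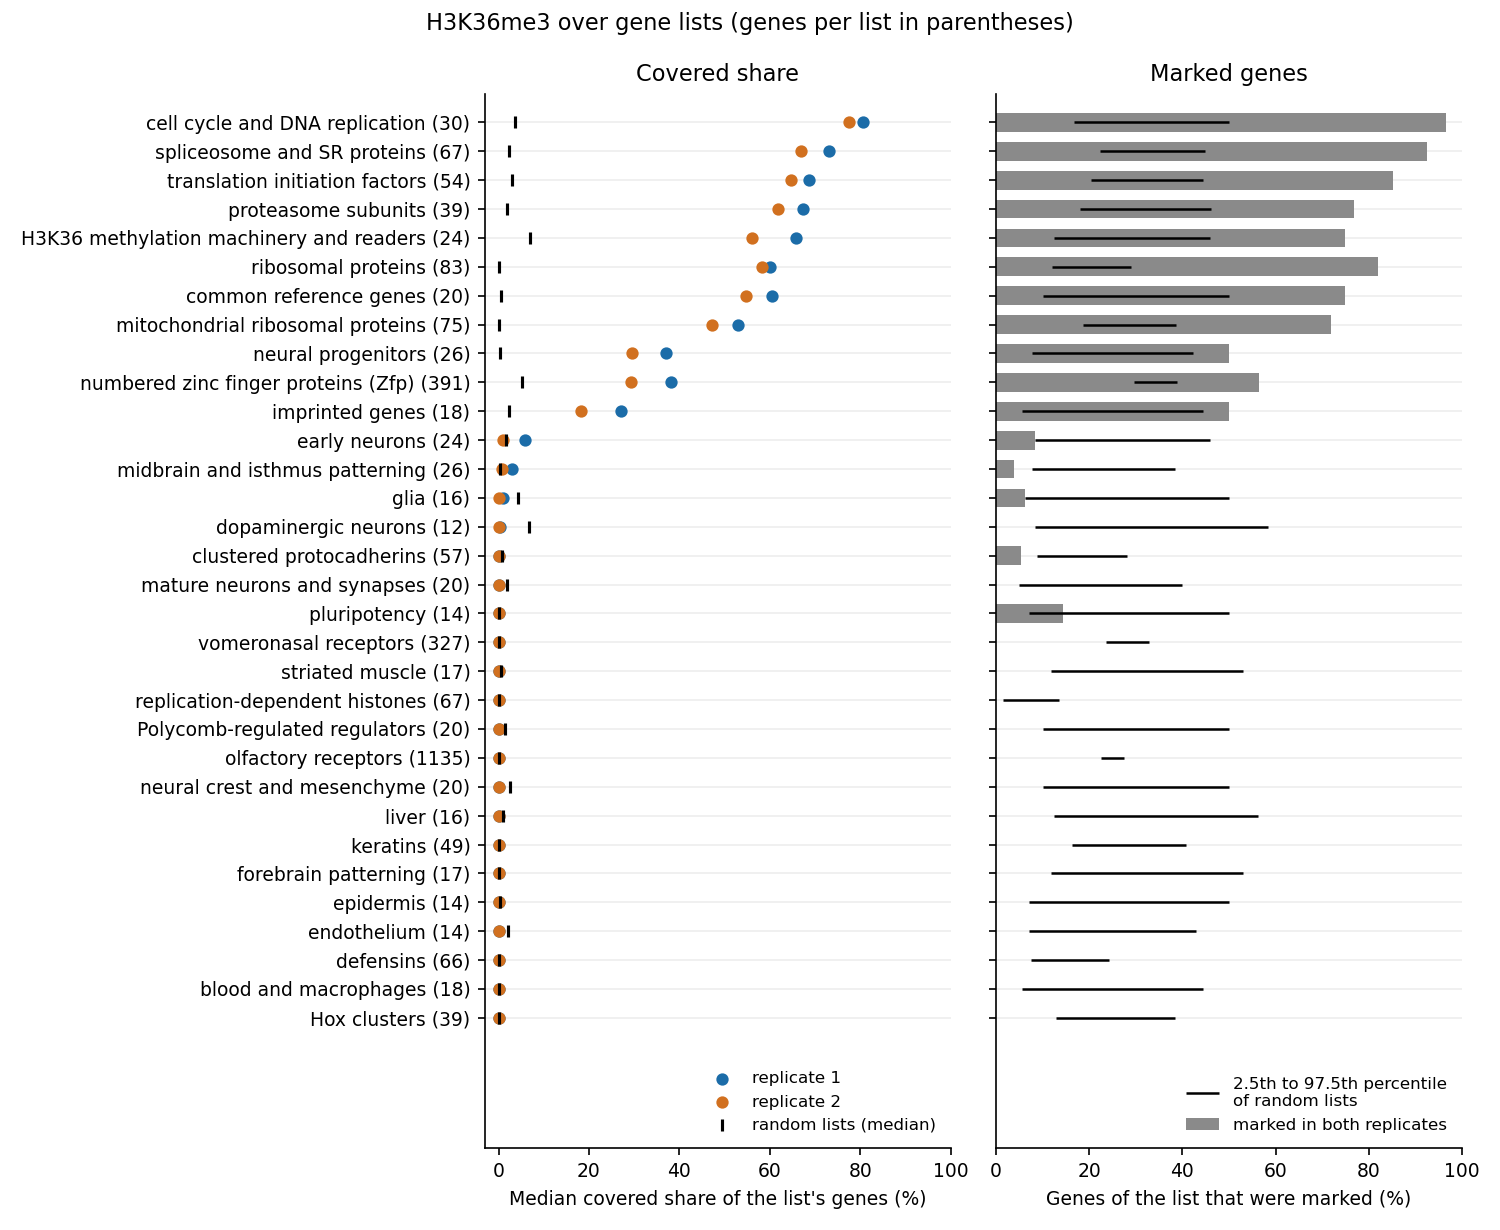
H3K36me3 over the 32 gene lists, with the median covered share of each list's genes per replicate on the left (percent; black ticks, median of 10000 length-matched random lists) and the share of genes marked in both replicates on the right (percent; black lines, central 95% of random lists). Cell cycle genes lead with 29 of 30 marked, neural progenitors have 13 of 26 marked, and 16 lists have no marked gene.

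Several developmental and clustered gene families were nearly free of the mark. All 39 Hox genes and all 20 Polycomb-regulated developmental regulators of other tissues, such as Cdx2 and Tbx5, held no base in a peak. Of 67 replication-dependent histone genes, which are intronless and highly active in dividing cells, 65 held no base in a peak and none was marked (random lists 1 to 9); Hist3h2a (3.01 ± 0.16%) and Hist1h2be (0.654 ± 0.925%) were the exceptions. None of 49 keratin and 66 defensin genes was marked. Def8 (26.9 ± 5.2%) was counted in the defensin list through its symbol only. Of 57 clustered protocadherin genes 3 were marked, Pcdhga7 (34.3 ± 12.4%), Pcdhgb4 and Pcdhga8. These share exons at the end of the cluster, and 21 of the 57 passed 25% in replicate 1 alone. Of 14 pluripotency genes Sall4 (60.6 ± 3.1%) and Lin28a (39.8 ± 8.7%), were marked, and Lin28a is also in the progenitor list, while Utf1 and Zfp42 stood at 0. Of 18 imprinted genes 9 were marked (random lists 1 to 8), with Nnat at 80.6 ± 3.4% and Igf2r at 53.8 ± 10.3%, while Igf2 and Ndn stood at 0. The imprinted list median of 23.8% lay at the 96.9th percentile. Among numbered zinc finger genes (Zfp), 221 of 391 were marked (random lists 116 to 152) with a median of 33.8%, above all random lists.

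Zinc finger genes also headed the ranking by covered share times signal value, as the mean of the ranks in both replicates, among genes of at least 10 kb. Of the 10 highest, 7 were zinc finger genes: Zfp90, Zfp606, Zfp110, Zfp68, Zfp354c, Zfp157 and Zfp334. Zfp606 (chromosome 7, 12478293 to 12496235) was covered over 90.0 ± 0.1% with signal values of 20.99 and 19.1, and Zfp90 over 86.3 ± 0.3% with 23.2 and 23.0. The other 3 were the splicing factor gene Sf1 (91.8 ± 0.1%), the RNA helicase gene Ddx17 (91.4 ± 0.5%) and the fatty acid synthase gene Fasn (90.5 ± 1.3%), which shared its mean rank with Zfp518b and was taken by symbol order. The median signal value of all marked genes was 6.79 in replicate 1 and 6.28 in replicate 2. Signal values are the authors' own per peak, and Zfp90, Zfp68, Sf1 and Ddx17 overlap other annotated genes.

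**Figure D2:**
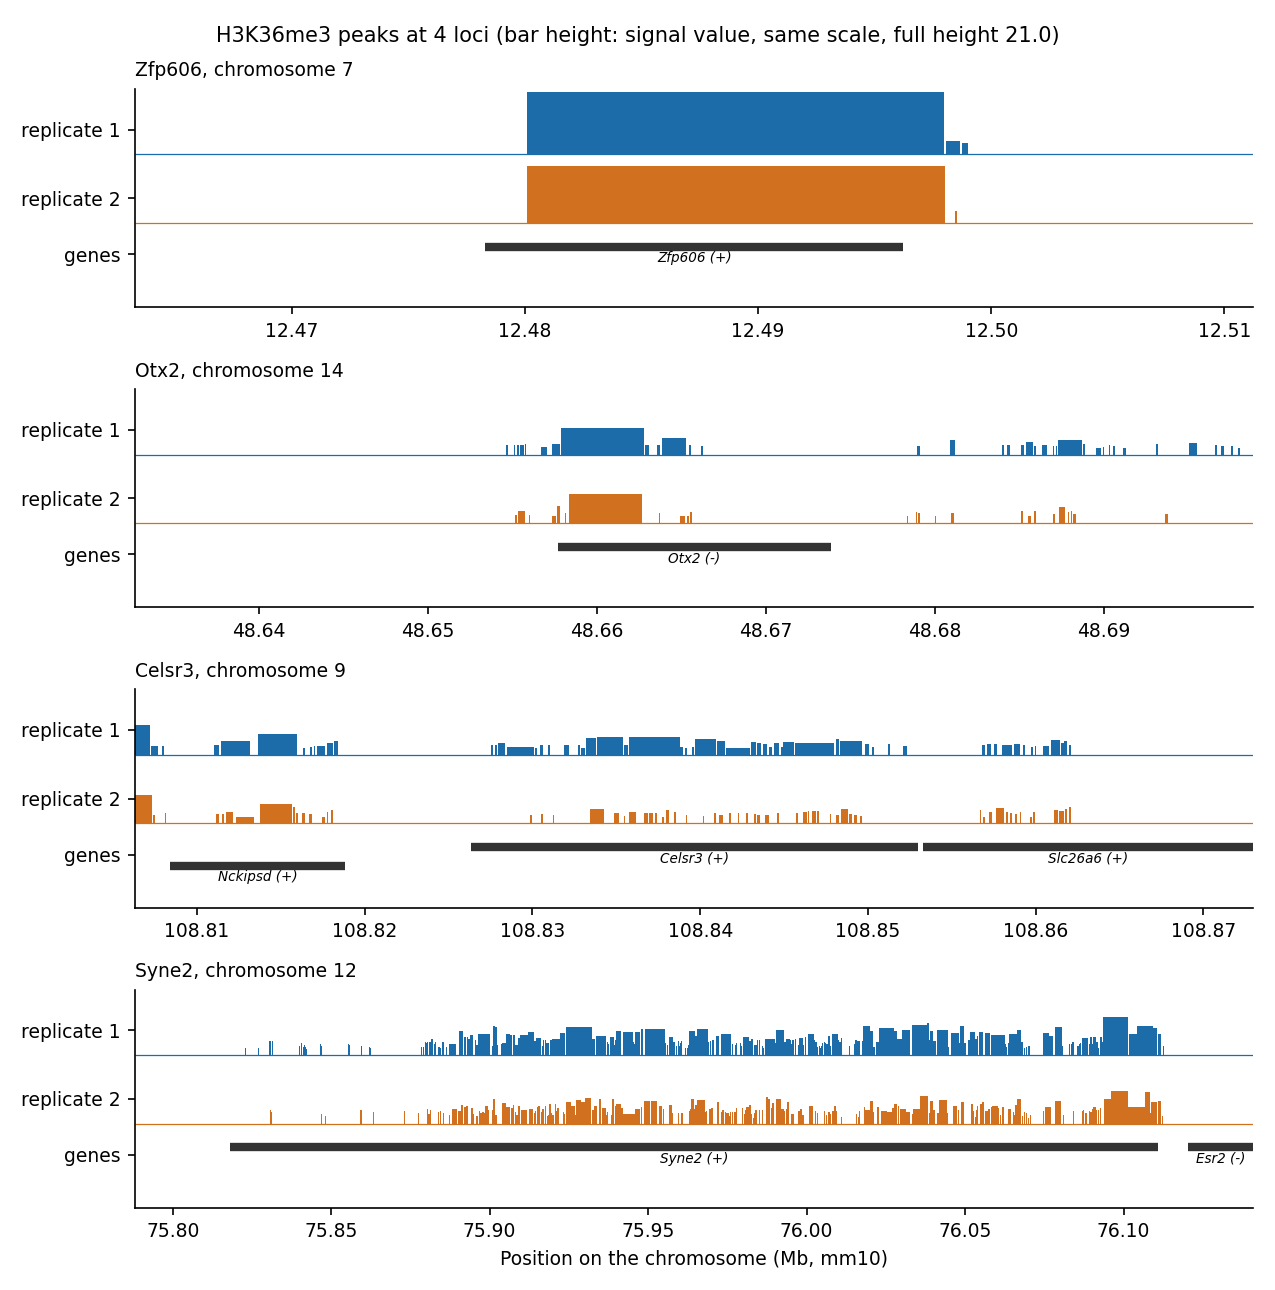
H3K36me3 peaks at Zfp606, Otx2, Celsr3 and Syne2 (position in Mb of mm10; bar height, signal value per peak on a common scale; replicate 1 above replicate 2; dark bars, protein-coding genes with their strand). Zfp606 is covered over 90.1% and 90.0% of its body, Otx2 over 43.7% and 32.1%, and Celsr3 over 70.1% and 23.2% in replicates 1 and 2.

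Along marked genes the mark was low at the start and rose towards the end. Over 4355 marked genes of at least 10 kb, the first of 10 equal parts of the gene was covered over 11.7 ± 2.5% (mean ± SD of both replicates), the second over 39.1 ± 6.5% and the ninth, the highest, over 76.0 ± 6.6%. The last part was covered over 71.3 ± 6.8%. Of the 5 kb downstream of the annotated end 31.9 ± 5.7% was covered, against 9.02 ± 1.44% of the 5 kb upstream. In the 9707 unmarked genes of at least 10 kb these shares were 8.63 ± 2.02% and 3.29 ± 0.63%. Flanks that lie in a neighbouring gene were not left out, so covered bases there may belong to other genes. The first covered base lay at a median of 2.25 kb from the start of the gene in replicate 1 and 2.59 kb in replicate 2. In the 1892 marked genes of at least 10 kb that overlap no other gene, exons were covered over 73.5% and introns over 62.3% in replicate 1. In replicate 2 they were covered over 66.0% and 52.5%. Exons and introns were not matched on position in the gene, along which coverage rose, so position cannot be separated from this difference. Over all 14062 protein-coding genes of at least 10 kb the share was 5.06 ± 0.88% in the 5 kb upstream, 4.996 ± 1.320% in the first part and highest in the last, at 29.6 ± 4.5%.

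**Figure D3:**
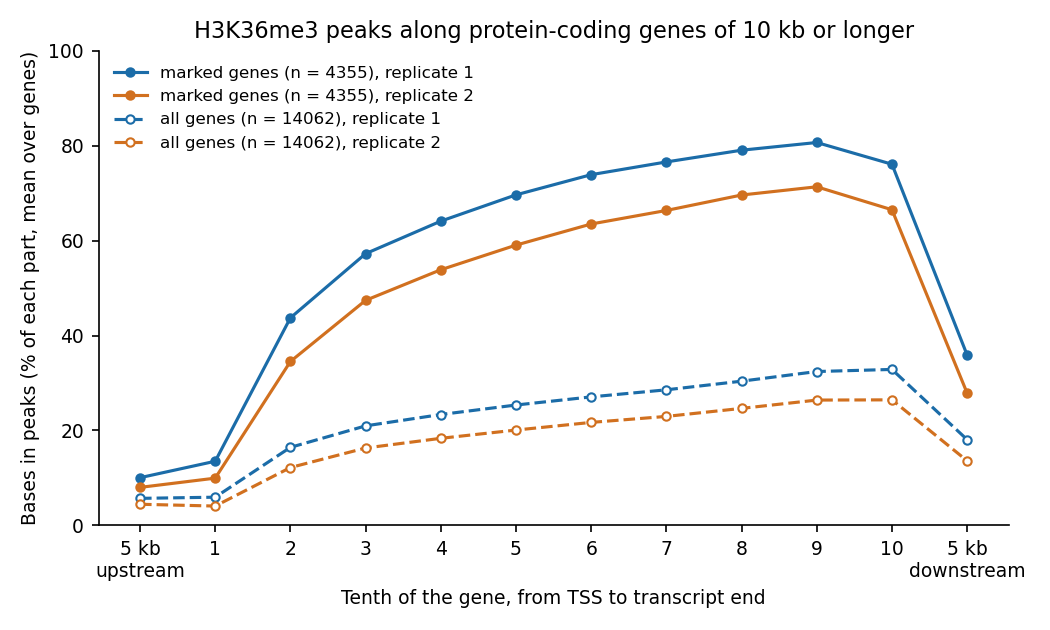
Share of bases in peaks (percent, mean over genes) in 10 equal parts of protein-coding genes of at least 10 kb and in 5 kb on either side, for marked genes (solid) and all genes (dashed), per replicate. In marked genes the share rises from 13.5% and 9.94% in the first part to 80.7% and 71.3% in the ninth in replicates 1 and 2.

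Covered bases lay almost entirely in protein-coding gene bodies, which held 94.3 ± 0.5% of them. Introns held 70.9 ± 1.3% of covered bases and exons 21.8 ± 1.6%, and both shares exceeded those of 100 circular shifts of the same peaks, by 1.68-fold and 5.27-fold. Promoters, within 1 kb of a transcription start site, held 3.01 ± 0.05%, which was 0.754-fold of the shifted peaks, and 6.59% when drawn within 2 kb. Intergenic sequence held 4.29 ± 0.33%, or 0.0863-fold. These differences were larger than the spread between replicates.

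Of the 5991 genes marked in replicate 2, 5973 were also marked in replicate 1, which covered most of them further. Of the genes marked in both, 95.4% had the higher share in replicate 1, by a median of 7.77 percentage points. Passing 25% in replicate 1 only were 1249 genes, and in replicate 2 only 18. The genes of at least 10 kb with the largest excess in replicate 1 were Celsr3, a cadherin of axon guidance (70.1% against 23.2%), Ncan, a brain proteoglycan (52.6% against 7.86%), Scg3, a secretory granule protein (53.5% against 10.9%), Fsd1 (64.7% against 25.1%) and Myt1, a neuronal transcription factor (43.5% against 4.95%). The largest excess in replicate 2 was at Lin28a (33.6% against 45.9%), followed by Rcn1, Sh3bp1, Six4 and Dusp5. Across genes the covered shares correlated with a Spearman rho of 0.967 and a Pearson r of 0.980, as a description, since genes are not independent replicates.

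**Figure D4:**
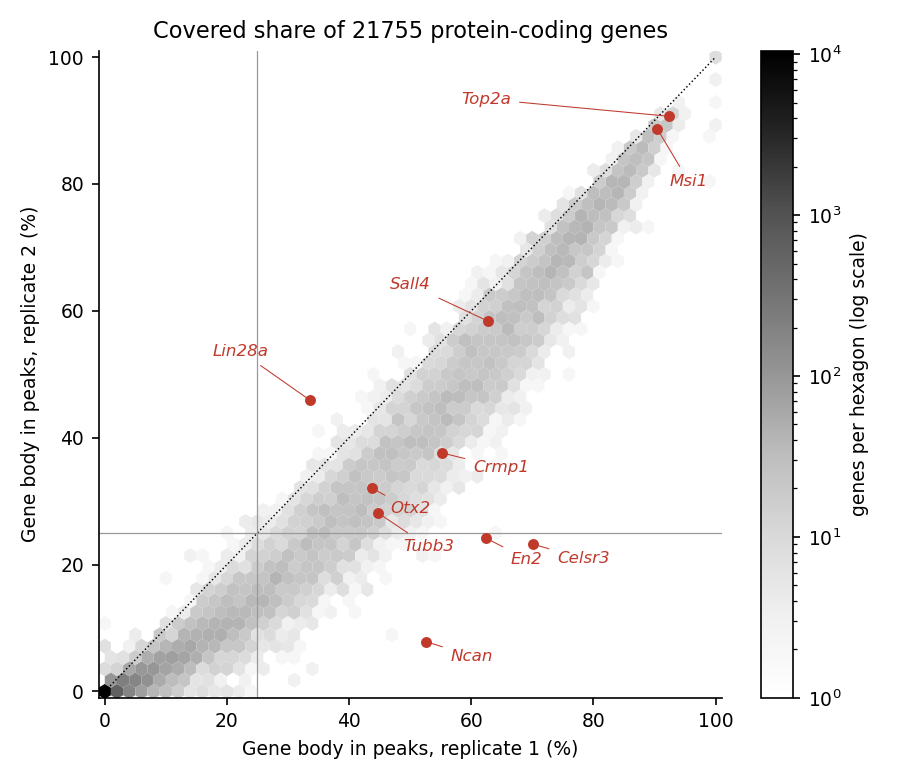
Covered share of the gene body (percent) of 21755 protein-coding genes in replicate 1 and replicate 2 (shading, genes per hexagon on a log scale; grey lines, 25%; dotted line, equal shares). Of the genes marked in both replicates 95.4% lie below the line of equal shares; Celsr3, Ncan and En2, which pass 25% in replicate 1 only, lie far below it and Lin28a (33.6% and 45.9%) above it.

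Of bases in peaks of 5 kb or more, 95.5% in replicate 1 and 99.4% in replicate 2 lay in peaks of the other replicate, against 19.9% and 66.6% of bases in peaks under 200 bp. After circular shifts, a comparison by width added after seeing the data, these were 4.89% and 6.86% for the wide and 4.60% and 6.33% for the narrow peaks. Peaks covered 152 Mb in replicate 1 and 112 Mb in replicate 2 (132 ± 28 Mb), or 5.77% and 4.24% of the genome, and their median width was 184 and 174 bp. Of replicate 1 peaks 54.2% met a replicate 2 peak by at least 1 bp, against 6.93% on average after circular shifts, and 87.9% of replicate 2 peaks met replicate 1, against 8.98%. Of peaks under 200 bp 29.3% of replicate 1 and 79.1% of replicate 2 met the other replicate, and of peaks from 200 bp to under 1 kb 78.0% and 98.6% did. All 2200 peaks of replicate 1 and all 1110 of replicate 2 that were 5 kb or wider met the other replicate, against 15.4% and 19.6% after shifts. The base-pair Jaccard index was 0.612, and the highest of 100 shifts reached 0.0479. The authors' replicated list held 184895 of the 304305 pooled peaks (60.8%), and the peaks it left out had a median width of 104 bp and 8.74% of the pooled bases. With reciprocal overlap of at least 50%, 24.4% and 29.3% of peaks were shared.

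The widest domain of the replicated list lay over Syne2, which encodes a giant protein of the nuclear envelope, at chromosome 12, 75877524 to 76070306 (193 kb, 84.0% of it in peaks). With signal values of at least 3 the widest was instead the domain over Usp34 and Ahsa2, and with joining at 10 kb one over Msi2. In the list as deposited, the next were over Usp34 and Ahsa2 on chromosome 11 (167 kb), Birc6 on chromosome 17 (167 kb), Mllt10 and Dnajc1 on chromosome 2 (153 kb), Ttc19 and Ncor1 on chromosome 11 (149 kb) and Rfx4, a transcription factor of neural progenitors, on chromosome 10 (149 kb). Domains over Myh10 and Ndel1, Wdfy3, Zfp462 and Eif4g3 completed the 10 widest, at 134 to 147 kb. Peaks no more than 3 kb apart were joined, which gave 23956 domains with a median width of 3.14 kb. The count is set by the joining distance, being 42503 at 1 kb and 12087 at 10 kb, where the widest spanned 392.4 kb.

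Marked sequence far from any annotated gene was rare. Domains more than 5 kb from every gene of any type numbered 300, and their peaks held 0.106% of covered bases. The widest, at chromosome 3, 17752769 to 17770745 (17.98 kb), lay 19.2 kb from Mir124-2hg, the host gene of a neuronal microRNA, and was covered over 46.5% in replicate 1 and 31.4% in replicate 2. The others among the 5 widest lay on chromosome 4 at 142457923 to 142470722 (12.8 kb), 111.4 kb from Gm13052, on chromosome 5 near D930016D06Rik (9.49 kb), on chromosome 4 at 31.4 kb from Elavl2 (8.33 kb) and on chromosome 17 near Gm5165 (7.99 kb). At 20 kb from any gene 95 domains were left, and the number was 469 with joining at 1 kb and 153 at 10 kb.

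Of 948 X-linked genes 81 were marked (8.54%) in these pools of both sexes, against 5892 of 20807 autosomal genes (28.3%), and the lowest autosome, chromosome 14, reached 20.6%. The X shares were 12.2% in replicate 1 and 8.65% in replicate 2, against 34.2% and 28.4% on the autosomes. Marked X-linked genes also had lower signal values, with medians of 5.32 and 5.09 in replicates 1 and 2 against 6.82 and 6.31 for marked autosomal genes. Peaks covered 1.37% and 0.830% of the X chromosome. The difference in marked share, -19.8 percentage points, exceeded the spread between replicates, and it was -12.8 points with a marked threshold of 50%.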

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

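Peaks on sequence outside the autosomes and X entered no comparison, and their numbers exceeded what a count of 0 allows, which is a low bar that says nothing of their source. The Y chromosome held 99 peaks in replicate 1 and 66 in replicate 2. Of 183 protein-coding Y genes 4 were covered in both replicates and 0 were marked: Ddx3y (14.7% and 7.88% of the gene body), Kdm5d (10.8% and 3.05%), Eif2s3y (1.21% and 1.90%) and Uty (2.32% and 0.619%). The embryo pools held both sexes, per the labels. Unplaced or unlocalized sequence held 33 peaks in replicate 1 and 12 in replicate 2.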

How the results depend on the processing

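No difference changed its sign and no called gene list changed its side under any alternative run. All 10 called lists were high, at the 99.97th percentile or above, and none was low by the median. A change of side therefore had little room to occur. Gene lists aside, 88 alternative values stayed close and 50 moved, where close meant within 1 SD of the replicates, within 1.5 times for a count, within the 95% binomial interval for a share without replicates, and no change at all for any other value. The number of marked genes was thus close in settings where their share moved. The cause of the moves was not tested except where the setting itself fixes them. The marked-gene counts per list below were added after seeing the data. With a −log10 q of at least 2, median peak width became 220.5 bp, replicate 1 and 2 peaks met the other replicate in 57.8% and 85.7% of cases, the Jaccard index was 0.624, rho across genes 0.970, marked genes 26.2% and sequence outside genes 284 kb. With signal values of at least 3 these were 224.5 bp, 59.2%, 83.2%, 0.624, 0.970, 26.1% and 266 kb, and the widest domain was 167 kb, over Usp34 and Ahsa2 in place of Syne2. With equal numbers of peaks they were 195.5 bp, 60.2%, 84.1%, 0.630 and 0.971.

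An overlap of 50% of the peak gave 37.7% and 79.0% shared peaks, and a reciprocal one 24.4% and 29.3%. Promoters of 2 kb held 6.59% and introns then 68.8% of covered bases. Leaving out each replicate in turn gave 27.5% to 33.2% of genes marked, and an X minus autosome difference of -21.9 to -19.7 percentage points. The replicated list gave 32.9% and -21.7 points, and the pooled list 34.8%. Profiles of genes of at least 50 kb rose by 45.6 points from the first to the last of 10 parts. Genes that overlap no other gene gave 2665 marked (fewer genes being tested), 23.1% of those tested, and an X difference of -15.0 points. Thresholds of 10% and 50% gave 36.4% and 15.1% marked (3277 genes at 50%), with an X difference of -12.8 points at 50%, and genes of at least 2 kb 29.2%. Joining at 1 kb gave 42503 domains, the widest 133.6 kb (Syne2), with 469 outside genes (356 kb). At 10 kb there were 12087, the widest 392.4 kb (Msi2), with 153 outside genes (289 kb). At 20 kb from any gene 95 domains (91.7 kb) were left.

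The calls of all 32 lists were unchanged by either peak threshold, the replicated list or leaving out each replicate. The summary of the low lists decided their call: with list means in place of medians 17 lists became low, among them dopaminergic neurons at the 0.04th percentile. Early neurons, not called by either, went from the 66.1st percentile by the median to 2.55 by the mean. Equal numbers of peaks made mature neurons low (1.96), and random lists not matched on length made both receptor lists low. Among genes that overlap no other gene, midbrain patterning became high (97.55th percentile) with 0 of 17 genes marked. No paired analysis was possible because the series holds 1 group. Unknown depth limits all differences between replicates.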

Other observations

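Chosen only after their results were seen were both tests of the neuronal genes and the test of X-linked signal values; the test of X gene content and both tests of the zinc finger genes were set before theirs.

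Of 4814 long intergenic noncoding RNA genes outside protein-coding genes, 48 were marked in both replicates. Mir17hg, the host gene of a microRNA cluster that promotes proliferation (chromosome 14, 115042879 to 115046727), was covered over 100% in both replicates. Malat1, an abundant nuclear RNA gene on chromosome 19, was covered over 72.8% and 62.7%, and D930016D06Rik on chromosome 5, a gene of 28.5 kb, over 81.6% and 70.4%. None of 209 antisense genes outside protein-coding genes was marked. These genes were chosen after their values were seen.

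Some of the strongest peaks met no protein-coding gene in either replicate, and the examples here were chosen after their values were seen. On chromosome 5 a peak of 300 bp at 23707214 to 23707513 had a signal value of 24.4 in replicate 1, and its counterpart in replicate 2 had 24.7. On chromosome 9 a peak at 124268568 to 124271684 had 19.5 in replicate 1 and its counterpart 15.5 in replicate 2. The chromosome 9 peak and its counterpart meet the long intergenic noncoding RNA gene Gm39469, which was itself marked (66.0% and 58.2%). The source of these peaks was not tested. On the X chromosome, Hcfc1 (87.2% and 86.3%), Med12 (83.8% and 72.4%) and Flna (77.2% and 74.7%) had high covered shares.

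Neuronal genes were covered less in replicate 2 than in replicate 1: 20 of 24 early neuron genes had the higher share in replicate 1 and 1, Nefl, in replicate 2, a direction shared by 21 of 26 progenitor, 26 of 30 cell cycle and 60 of 67 spliceosome genes, so only the size of the difference was tested. The list's median difference of 4.14 percentage points lay at the 98.75th percentile of lists matched on covered share and signal value in the pooled list (central 95% 1.10 to 3.93), and the neural progenitor list, at 3.97, at the 0.87th percentile of its own (10.1 by the mean). However, 6 of the 9 lists examined lay outside that range, among them the ribosomal (0), spliceosome (0.27), cell cycle (0.33) and zinc finger (99.3) lists, so matched lists do not give the difference to be had without a change in neuronal genes. A lower yield of peaks in replicate 2 over weakly covered genes and more neuronal chromatin in the replicate 1 pool therefore cannot be told apart for these genes. The labels give no difference in stage or dissection between the pools, and read depth is unknown.

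Fewer X-linked than autosomal genes were marked. Taken as how broadly its genes are used, the gene content of the X chromosome was argued against as the whole cause. In 7 lists of broadly used genes 4 of 11 X-linked genes were marked (36.4%, exact 95% interval 10.9 to 69.2%), against 299 of 356 autosomal genes (84.0%). The 4 were Eif2s3x, Rps4x, Pgk1 and Eif1ax, and the others Rpl39, Hprt, Rpl10, Pola1, Rpl36a, Hnrnph2 and Psmd10. These genes were not matched on length, so a difference in gene length was not excluded. Pola1 spans 327.4 kb, and 1.70% of all genes of 200 kb or longer were marked. Lower peak signal on the X chromosome cannot be told apart from other causes of weaker coverage, because signal value and covered share are readings of the same peaks: the 81 marked X-linked genes had median signal values of 5.32 and 5.09 where length-matched marked autosomal genes had 6.99 and 6.43, at the 0th percentile of 10000 draws in both replicates. No biological explanation was tested.

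Numbered zinc finger genes stood among the most strongly covered genes, with 14 of the 30 highest and 18 of the 100 highest by covered share times signal value, while they made up 3.97% of the 4355 marked genes of at least 10 kb. Their long exons were not excluded as the whole cause. The 173 marked Zfp genes had a median of 4.43, at the 98.6th percentile of other marked genes matched on gene length and longest exon. The matched median was 3.93 and the upper limit of the matched range 4.36, so the margin was narrow. Position was not matched, and some Zfp genes are neighbours, such as Zfp606 and Zfp110 on chromosome 7. If neighbours are alike, the matched range is too narrow. Reads shared between paralogs were argued against. A median of 0.0902% of the 50-base words of the Zfp transcripts occurred in transcripts of other genes. That share did not rise with strength (rho = -0.0768 across genes). In 17 of these genes at least 10% of the words were shared. No biological explanation was tested, and introns were not searched for shared sequence.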
